A study of Ovis aries with 96 samples.

How the data were processed

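Amplicons of the 18S rRNA gene were sequenced from rumen fluid of 16 fistulated sheep, 8 per diet and 6 times of day, which gave 96 samples. Per the series description, the sheep weighed about 65 kg at about 3.5 years of age, were held on hay for 14 days, and were then fed for 30 days with hay or with forage and concentrate at 40:60, offered at 8:00. Samples were taken at intervals of 4 hours from 2:00 to 22:00 without fasting. Per the labels' protocols, DNA was isolated from 1 mL of frozen fluid with a stool DNA kit and paired reads were made on a NovaSeq instrument. The authors deposited 1 table of raw counts per sequence feature and sample, with a taxonomy for each feature. R 4.2 is named in the submitters' processing notes. The primers, the denoising tool, the chimera filter, the taxonomy database and any count minimum are not given in the sources used here. The lowest total of a feature was 51 counts and the lowest count above 0 was 2. No genome applies, and the gene table at hand was not used, since the features are marker sequences named by the taxonomy column alone.

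Samples were grouped by the diet and time in their labels, and the number in the title was taken as the sheep, since the series description states that every sheep was sampled at each time. Samples of the same sheep at different times shared deviations from their group mean over 10 features with counts in at least 48 samples, with a mean correlation of 0.313 on hay (-0.0270 between different sheep) and 0.144 on grain (-0.0238). The sheep was the replicate for diet and the block for time. No samples were identical, and the closest pair differed by 44.9 times the chi-square per degree of freedom that sampling alone gives, so none were merged. No batch is named in the labels. A count of 0 over the libraries of a diet allows a share of up to 0.000117%, from 3 counts. Such floors cover counting error only, since amplicon reads without molecular identifiers are not independent molecules. A percent of counts is relative to all ciliate reads, and 18S gene copies differ between ciliates, so it is neither a cell count nor a share of biomass.

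Counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood tests after TMM scaling and filterByExpr with a count minimum of 10 and a total of 15. For diet, the counts of the 6 samples of each sheep were summed. For time, the 5 time coefficients were tested with sheep as a block, within each diet and then as diet by time over all 96 samples, and each time point was fitted on its own 16 samples. P-values were adjusted by the Benjamini-Hochberg method over the features tested, 16 for diet, 20 for time on hay, 17 for time on grain, 30 for diet by time and 9 or 10 at a time point, and calls were made at 0.05. Features that passed the filter held 97.6% of counts in the diet test. The median log2 fold change of grain over hay was 0.29 with TMM, 0.32 with total-sum scaling, -0.00 with DESeq2 and -0.16 on centred log-ratios. Fold changes between diets are those of TMM unless another measure is named. Folds between times are ratios of the highest to the lowest hourly mean percent, with both hours picked from the same data. The split of higher and lower calls was 3 and 2 with TMM, 4 and 2 with total-sum scaling, 3 and 4 with DESeq2 and 5 and 4 on centred log-ratios.

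Genera at a mean of at least 0.01% were tested as percents of counts, between diets by a two-sided exact permutation over the 12870 assignments of 16 sheep and over time by 100000 permutations of times within sheep. Benjamini-Hochberg adjustment ran over 3 genera or, for the taxon lists, over the 4 with counts. Bray-Curtis distances were tested by PERMANOVA, exactly for diet and with 10000 permutations within sheep for time. Features seen were counted after thinning each sample to 42372 counts. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, limma 3.58.1 and DESeq2 1.42.0 as alternatives, and matplotlib 3.10.9 for plots.

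The design, the tests, the alternative settings, the taxon lists and the rule for named features were fixed before the data were examined. The rule names each genus that passes a test or belongs to a taxon list with a mean of at least 0.1% in either diet, up to 25, each list with counts, features that differ between diets with a mean of at least 0.1% in the higher diet, up to 10 per direction, and the 6 features with the smallest p among those passing each time test. The lists were Isotrichidae, other vestibuliferan and archistome ciliates, Entodiniinae, Ophryoscolecinae, Diplodiniinae, genera of type A and of type B faunas, rumen flagellates and amoebae, anaerobic rumen fungi, yeasts and moulds, plants, animals, and bacteria and archaea. Alternatives were total-sum scaling, DESeq2, limma on centred log-ratios with a pseudocount of 0.5, other filters, thinning, a depth covariate, cosine and sine terms with a period of 24 hours, ranks, genera in place of features, other distances, fits with and without the sheep number as a block, and each sheep left out in turn. Permutation tests on percents of features, joint counting of Ent1 and Ent3, Ent1 at the level of Ent3 in grain libraries where it was at 0, means without the highest library, and omission of hay sheep 4 and 8 or of the 10:00 library of hay sheep 4 were added after the data were seen.

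The scripts were tested on simulated counts drawn from the real features, with 4 features changed, in 25 datasets per setting. Each feature had a single mean share over the libraries, with no sheep effect, and library totals were held. A change in an abundant feature therefore shifted the shares of unchanged ones, and calls of these were counted as false. The rates need not hold for the real data. For diet (16 features), edgeR recovered 52% of features changed 4-fold and 64% of those changed 8-fold, with 1 false call in 25 datasets without change. For time it recovered 43% and 49% on hay (20 features) and 22% and 38% on grain (17 features), with 14 and 8 false calls in the 25 unchanged datasets. For diet by time (30 features) it recovered 9% and 19%, with 45 false calls in the 25 unchanged datasets. With 4-fold changes present, false calls made up 11.9% of all calls for diet, 37.7% for time on hay, 35.3% for time on grain and 77.5% for diet by time. The permutation tests on percents recovered 100% of 4-fold changes between diets, 97.5% over time and 85% of differences between time courses, in 10 datasets of 20 features, with 1, 0 and 0 false calls in as many unchanged datasets and 4, 0 and 2 in those with 4-fold changes. Those datasets were percents with the real means but a chosen log-normal spread and no zeros, and the 4 most abundant features were always the ones raised. Their rates therefore cannot be set against those of edgeR, nor taken as the power on the real data. The unassigned Haptoria feature, in 2 libraries, entered no comparison of its own, and features in few libraries were left out of the tests by the filter.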

Results

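The series profiled the ciliate protozoa of the sheep rumen by sequencing amplicons of the 18S rRNA gene, the gene for the small ribosomal subunit RNA of eukaryotes. Rumen fluid came from 16 fistulated sheep, 8 kept on hay and 8 moved to a grain-based diet with forage and concentrate at 40:60. Each sheep was sampled at 2:00, 6:00, 10:00, 14:00, 18:00 and 22:00, and feed was offered daily at 8:00. The 96 samples, 48 per diet, held 5120874 counts over 214 sequence features. Sample totals ran from 42372 to 61993 with a median of 53599, and averaged 53272 ± 4651 (SD) on hay and 53413 ± 3889 on grain. Entodinium, a genus of small ciliates that take up starch and bacteria, held 169 features and 86.1% of all counts. Dasytricha, a holotrich ciliate that uses soluble sugars, held 24 features and 10.1%. Polyplastron, a large ciliate that digests plant fibre and preys on other protozoa, held 17 features and 3.79%. A further 3 features were assigned no deeper than Trichostomatia and 1 no deeper than Haptoria. Features are called by genus and rank of abundance, so that Ent1 is the most abundant Entodinium feature, Das1 and Pol1 those of Dasytricha and Polyplastron, and Tri2 the second of the unassigned Trichostomatia. The 8 most abundant features averaged 96.6% of a sample.

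The first comparison asked which ciliate features differed between sheep on hay and on grain. Ent1, the leading feature on hay, made up 46.7% ± 14.4 (SD, n = 8 sheep) of counts on hay and 4.77% ± 4.52 on grain. It was 10.9-fold lower on grain, with 8 of 8 grain sheep below every hay sheep, but had 0 counts in 31 of 48 grain libraries. With each of those libraries given as much Ent1 as it held Ent3, a setting added after the data were seen, Ent1 was at 17.3% ± 5.64 on grain (exact permutation p = 0.000777). The ratio of the mean percents of hay and grain was then 2.69, a measure unlike the 10.9-fold, which is after TMM scaling. Library totals were not rescaled for the added counts, so 17.3% is higher and 2.69 lower than rescaled totals would give. Ent2, the leading feature on grain, was at 23.4% ± 8.99 on grain against 5.45% ± 2.93 on hay, 4.26-fold higher, and Ent5 at 18.3% ± 5.40 against 3.24% ± 2.91, 6.12-fold higher. Both were higher in 8 of 8 grain sheep than in any hay sheep. Ent8 was lower on grain, at 0.264% ± 0.196 against 1.17% ± 0.708, 5.10-fold, with 7 of 8 grain sheep below every hay sheep.

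In edgeR's quasi-likelihood test on counts summed per sheep, 5 of 16 features passed a Benjamini-Hochberg adjusted p of 0.05, 3 higher and 2 lower on grain, and 6 had an unadjusted p under 0.05. The log2 fold changes of grain over hay were -3.45 (SE 0.96, adjusted p = 0.00701) for Ent1, 2.09 (SE 0.36, 9.44e-05) for Ent2, 2.61 (SE 0.44, 9.44e-05) for Ent5 and -2.35 (SE 0.51, 0.00106) for Ent8. In the deposited table Ent1 is c36ff400cf93eba217cff58ccc01803e and Ent5 is 1681d1504afe3105214da074b3a71d83. The fifth feature was Tri2, which lies below the abundance set for naming and was chosen after its values were seen. It had 0 counts on hay and 342 counts in 24 grain libraries from 8 of 8 sheep (adjusted p = 9.44e-05). By genus, 4 of 11 tested Entodinium features passed, and the same number when adjusted over the list alone. None of 2 Dasytricha features and 0 of 1 Polyplastron feature passed over all features or adjusted over the list alone, and 1 of 2 Trichostomatia features passed both ways.

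Features that missed the threshold in edgeR included Ent6, at 8.46% ± 1.62 on grain and 5.70% ± 0.975 on hay, and Ent9, at 0.289% ± 0.173 and 0.0310% ± 0.0444 (adjusted p = 0.150 for both). Ent3, Ent4, Das1 and Pol1 had means of 11.2%, 10.1%, 11.2% and 3.59% on hay and 14.5%, 14.8%, 7.92% and 3.85% on grain, with adjusted p of 0.807, 0.150, 0.217 and 0.836. An exact permutation test of the sheep's percents, added after the data were seen, called 8 features, among them Ent6 (adjusted p = 0.000829) and Ent9 (adjusted p = 0.000497). Without hay sheep 4 and 8, chosen for their low Ent1, edgeR called 12 features, and 5 of them were those named above. Ent7 and Ent10, not among the 16 tested and chosen after their values were seen, had 0 counts on hay. Ent7 held 48750 counts in 9 libraries of 5 grain sheep and Ent10 3036 counts in 8 libraries of 6 grain sheep. Where present on grain, Ent1 had at least 1763 counts, and Ent7 was at least 1.34 times Ent3.

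**Figure D1:**
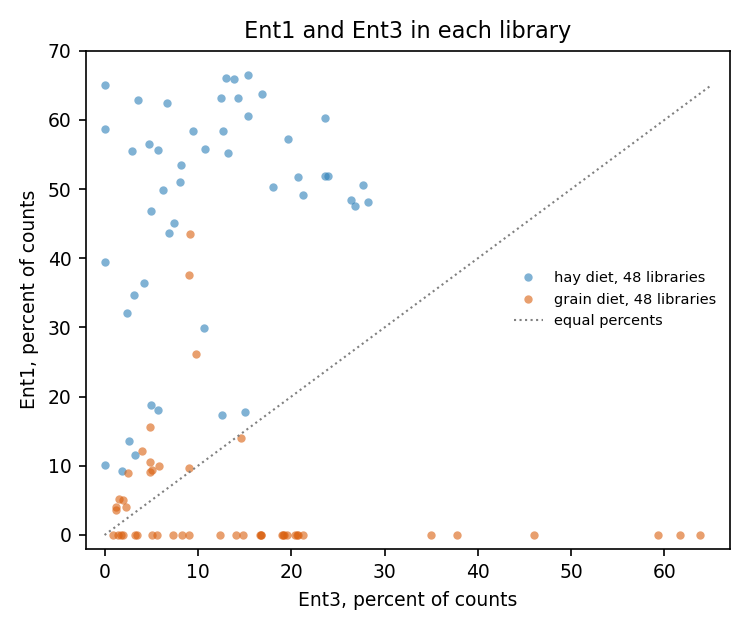
Percent of counts of Ent1 (vertical axis) against Ent3 (horizontal axis) in each of 48 hay libraries (blue) and 48 grain libraries (orange), with a dotted line of equal percents. In grain libraries Ent1 was either at 0, in 31 of 48, or at no less than 0.958 times Ent3.

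**Figure D2:**
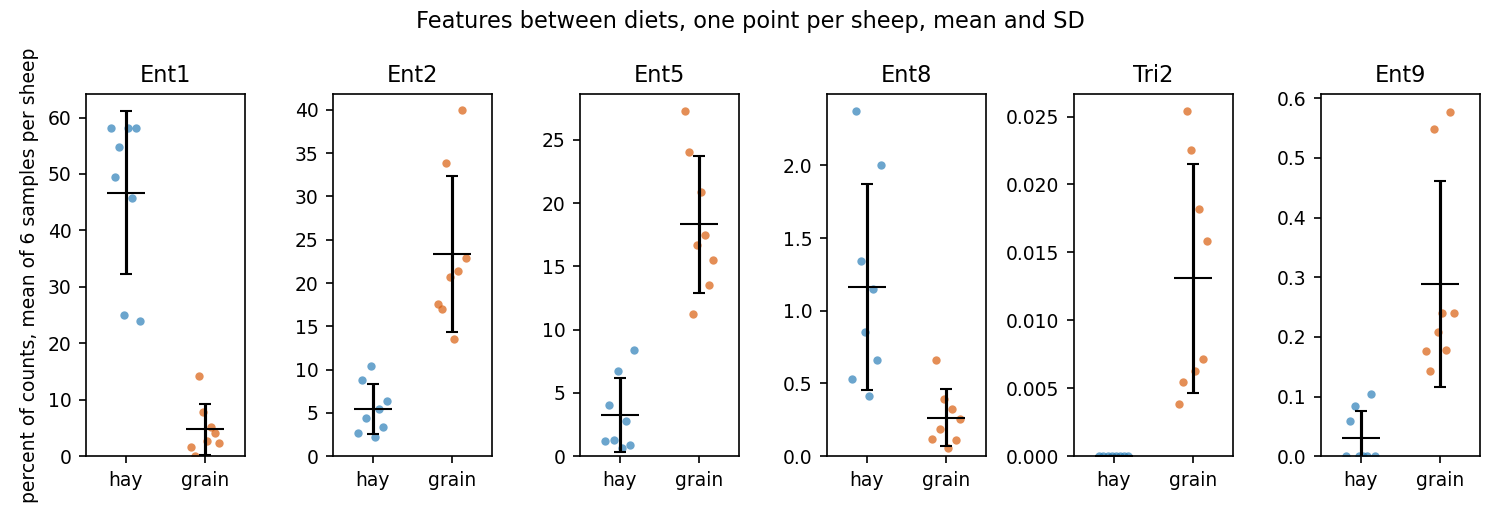
Percent of counts of Ent1, Ent2, Ent5, Ent8, Tri2 and Ent9 on hay and on grain, 1 point per sheep as the mean of its 6 samples, with the mean and SD of 8 sheep in black and separate linear axes from 0. Ent1 was at 46.7% on hay and 4.77% on grain, and hay sheep 4 and 8 lie apart at 25.0% and 23.9%.

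No genus passed the test between diets. Entodinium averaged 84.7% ± 3.61 (SD, n = 8) on hay and 87.6% ± 4.26 on grain (exact permutation p = 0.178, adjusted p = 0.267). Dasytricha averaged 11.6% ± 2.89 and 8.55% ± 3.84, with 5 of 8 grain sheep below every hay sheep (exact permutation p = 0.0977, adjusted p = 0.267). Polyplastron averaged 3.64% ± 3.12 and 3.85% ± 0.932 (exact permutation p = 0.899). The two-sided exact test over 12870 assignments of the sheep called 0 of 3 genera, with 0 at an unadjusted p under 0.05, and edgeR on genus counts also called 0, with 0 unadjusted. On centred log-ratios 2 genera passed, Dasytricha with a shift of -0.58 and Polyplastron with 0.57 on the log2 scale (exact adjusted p = 0.00606 for each). Without grain sheep 5, Dasytricha on percents differed by -4.16 points (exact adjusted p = 0.0191), which made 1 call.

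Of the 13 taxon lists, 4 held counts. Isotrichidae, here Dasytricha alone, had 11.6% on hay and 8.55% on grain (exact permutation p = 0.0977, adjusted p = 0.356), and Entodiniinae, here Entodinium alone, 84.7% and 87.6% (adjusted p = 0.356). Diplodiniinae and the genera of type A faunas both came down to Polyplastron, at 3.64% and 3.85% (adjusted p = 0.899). The exact test called 0 of these lists, with 0 at an unadjusted p under 0.05, and 1 without grain sheep 5. The other 9 lists held 0 counts in 96 samples. They were other vestibuliferan and archistome ciliates, Ophryoscolecinae, the genera of type B faunas, rumen flagellates and amoebae, anaerobic rumen fungi, yeasts and moulds, plants, animals, and bacteria and archaea. All features in the table are ciliates, and the primers, the taxonomy database and any filter of taxa before deposit are not known. These zeros therefore do not show that the organisms were absent from the rumen.

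The community of features separated by diet. Diet took 65.2% of the variation of Bray-Curtis distances between sheep (exact permutation p = 0.000155, the smallest the assignments can give). The mean distance was 0.235 within hay, 0.244 within grain and 0.533 between diets. On genera, diet took 13.5% and did not pass (exact permutation p = 0.131). Shannon diversity of features was 1.56 ± 0.169 (SD, n = 8) on hay and 1.72 ± 0.0366 on grain, higher by 0.162 on grain (exact permutation p = 0.0204). The sizes of the Shannon difference and of the diet share changed with the treatment of libraries with Ent1 at 0, but both still passed. With Ent1 and Ent3 counted as one the difference was 0.385 and diet took 63.6% of the variation, and with Ent1 at the level of Ent3 in those libraries they were 0.251 and 58.2% (exact permutation p = 0.000777 and 0.00109 for Shannon diversity and 0.000155 for diet in both), both added after the data were seen. On genera the difference was -0.0332 and did not pass (exact permutation p = 0.387). The number of features seen in 42372 counts was 15.7 ± 1.69 on hay and 14.6 ± 1.64 on grain (exact permutation p = 0.201).

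The next comparison asked which ciliates varied over the day in sheep on hay. Entodinium was highest at 2:00, at 93.0% ± 2.49 (SD, n = 8), and lowest at 10:00, at 68.9% ± 15.7, with the same order in 8 of 8 sheep. Dasytricha moved the other way, from 5.49% ± 1.70 at 2:00 to 20.4% ± 14.1 at 10:00, 3.71-fold higher, in 7 of 8 sheep. Percents of genera share a total, so these opposite courses are not independent results. Polyplastron was at 1.49% ± 1.10 at 2:00 and 10.7% ± 17.5 at 10:00, with medians of 1.07% and 3.79%, and higher at 10:00 in 6 of 8 sheep. Within Entodinium, Ent3 was at 23.9% ± 4.55 at 2:00 and 2.61% ± 1.98 at 14:00, 9.15-fold apart and in that order in 8 of 8 sheep. Ent1, the main hay feature, was between 41.0% and 51.9% at all 6 times and did not pass the test (edgeR adjusted p = 0.226). The hours given for a taxon, here and on grain, are those of its highest and lowest mean in the same sheep. Folds and sheep counts between these hours are raised by that choice and are not a test. Ent1 itself was higher at its peak hour than at its lowest in 7 of 8 sheep.

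Time of day took 53.3% of the within-sheep variation of Entodinium (permutation adjusted p = 0.000150), 34.3% of Dasytricha (0.00898) and 20.8% of Polyplastron (0.0124). The library of hay sheep 4 at 10:00 held 52.7% Polyplastron. Pol1 averaged 10.4% ± 16.9 at 10:00 and 4.60% ± 4.76 (n = 7) without that library, and without that sheep Polyplastron did not pass (permutation adjusted p = 0.0601), nor without sheep 3 (0.0796). Without sheep 1 neither Dasytricha nor Polyplastron passed (0.0509 each), and on centred log-ratios only Entodinium did. In edgeR 6 of 20 features passed and 7 had an unadjusted p under 0.05, namely Das1 (20.1% ± 13.9 at 10:00 against 5.36% ± 1.58 at 2:00, higher in 7 of 8 sheep), Pol1, Das3, Ent3, Ent18 and Ent5. Their edgeR adjusted p were 0.00477, 0.00477, 0.00611, 0.0249, 0.0316 and 0.0477 in that order. Das3 averaged 0.562% ± 1.05 at 22:00, or 0.218% ± 0.418 (n = 7) without the library of sheep 8 at 2.97%, and 0 at 10:00. Ent18 averaged 0.121% ± 0.130 at 2:00 and 0 at 14:00, and Ent5 4.69% ± 4.45 at 14:00 and 1.52% ± 1.90 at 2:00, or 0.871% ± 0.516 (n = 7) at 2:00 without sheep 8. By genus, 2 of 2 Dasytricha and 1 of 1 Polyplastron features passed both ways, and 3 of 17 Entodinium features passed over all features but 0 when adjusted over the list alone. In simulated data with 4-fold changes and no sheep effect 37.7% of this test's calls were false. The edgeR count was 0 without sheep 6, 1 without sheep 3, 2 without sheep 2 or 4 and 3 without sheep 7, and was 10 without sheep 1. It was 0 with limma on centred log-ratios, where 5 had an unadjusted p under 0.05, 3 with DESeq2, and 2 without the 10:00 library of sheep 4. With Ent1 and Ent3 counted as one, also added after the data were seen, 5 passed, of which 2 were shared, and Das1 (adjusted p = 0.160), Pol1 (0.0684) and Ent5 (0.580) did not pass. Ent3 had the firmest course in a permutation test on percents, added after the data were seen, with 81.8% of its within-sheep variation taken by time (adjusted p = 0.000200). Das1 and Das3 passed there too (0.0313 and 0.0334), as did Ent9 (0.0334), which edgeR did not call, and Pol1, Ent18 and Ent5 did not.

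**Figure D3:**
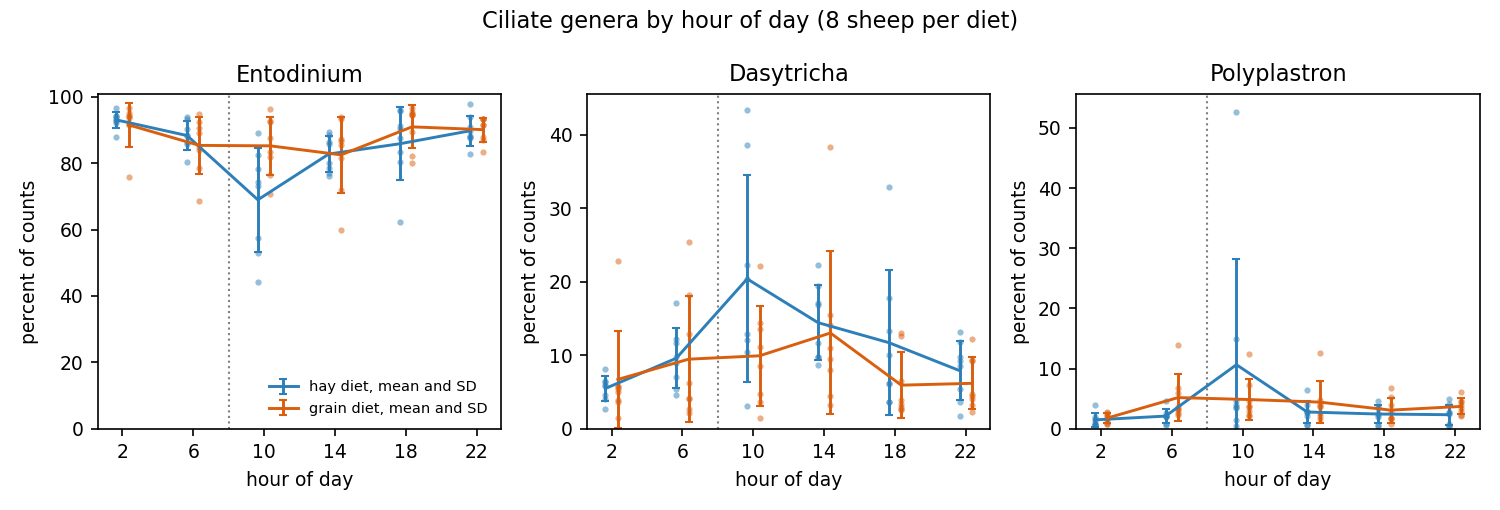
Percent of counts of Entodinium, Dasytricha and Polyplastron against hour of day, with 1 point per sample and lines for the mean and SD of 8 sheep on hay (blue) and on grain (orange). The dotted line marks feeding at 8:00, and Entodinium on hay goes from 93.0% at 2:00 to 68.9% at 10:00.

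The same comparison was made in sheep on grain. Ent5 was at 36.2% ± 15.6 (SD, n = 8) at 10:00 and 4.79% ± 3.27 at 22:00, 7.55-fold apart, in 8 of 8 sheep. Ent4 ran opposite, at 29.0% ± 12.9 at 22:00 and 7.94% ± 4.51 at 10:00, 3.66-fold apart, in 8 of 8 sheep. Percents share a total, so a fall of Ent5 raises the share of Ent4, and the courses are not independent. Ent3 stood at 36.1% ± 22.1 at 2:00 and 5.15% ± 7.03 at 14:00, 7.01-fold apart, in 7 of 8 sheep, and at 14:00 was at 2.84% ± 2.85 (n = 7) without sheep 2. Ent6 was at 11.4% ± 2.80 at 14:00 and 4.67% ± 2.21 at 2:00, 2.45-fold apart, in 8 of 8 sheep, and Ent8 at 0.627% ± 0.627 at 10:00 and 0 at 18:00, in 7 of 8 sheep.

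In edgeR 6 of 17 features passed over time on grain and 9 had an unadjusted p under 0.05. The adjusted p were 1.44e-08 for Ent8, 7.22e-08 for Ent5, 3.69e-05 for Ent3, 0.000130 for Ent4 and 0.00643 for Ent6. The sixth, Ent10 (0.0198), averaged 0.532% ± 1.17 at 10:00 and 0 at 2:00, higher in 4 of 8 sheep. The library of sheep 8 held 3.41% at 10:00, and the other 7 averaged 0.121% ± 0.163. All 6 were among 13 tested Entodinium features, and 6 passed when adjusted over the list alone. Neither of 2 Dasytricha features passed either way, and 0 of 1 Polyplastron feature passed over all features but 1 when adjusted over the list alone. In simulated data with 4-fold changes and no sheep effect 35.3% of the calls of the grain test were false. Ent6 did not pass with DESeq2 (adjusted p = 0.897), with limma on centred log-ratios (0.840), or without grain sheep 1 (0.0531). Ent10 did not pass with DESeq2 (0.908), and the count was 10 without grain sheep 3 or 4. The permutation test on percents called 7 features, kept Ent3, Ent4, Ent5, Ent6 (adjusted p = 0.000170) and Ent8 but not Ent10 (permutation p = 0.0954 before adjustment), and added Ent1 (adjusted p = 0.00470) and Tri2 (0.0256). Ent1 on grain averaged 16.3% ± 17.5 at 18:00 and 0.503% ± 1.42 at 6:00, with 3 and 7 of 8 libraries at 0. With libraries at 0 given the level of Ent3, also added after the data were seen, its highest mean was 36.0% ± 22.2 at 2:00, against 25.0% ± 15.8 at 18:00. Library totals were not rescaled for the added counts. This overstates filled libraries rich in Ent3, such as sheep 4 at 2:00 with 63.8% Ent3, and so the lead of 2:00. The hour of the Ent1 peak is thus not settled. Over 3 genera the permutation test called 0 on grain, with 0 at an unadjusted p under 0.05, and the adjusted p were 0.260 for Entodinium, 0.262 for Dasytricha and 0.260 for Polyplastron. Polyplastron averaged 5.19% ± 3.85 at 6:00 and 1.78% ± 0.798 at 2:00, in that order in 8 of 8 sheep.

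Over all features, time of day took 18.8% of the variation of Bray-Curtis distances on hay, where differences between sheep took 45.6%. On grain it took 35.7%, and differences between sheep 20.5%. Both passed a permutation test of times within sheep (p = 1e-04, the smallest 10000 permutations can give). On genera the share on grain was 15.0% and did not pass (permutation p = 0.125). Shannon diversity varied over the day on grain, at 1.81 ± 0.0486 (SD, n = 8) at 14:00 and 1.53 ± 0.241 at 2:00 (permutation p = 0.00722), and did not pass on hay (permutation p = 0.330). Both depended on the treatment of Ent1 and Ent3. On grain it did not pass with Ent1 at the level of Ent3 where it was at 0 (permutation p = 0.0861, with 23.0% of within-sheep variation in place of 35.4%). With Ent1 and Ent3 counted as one it still passed on grain (permutation p = 0.00448, 36.7%), and it passed on hay too (permutation p = 3.00e-05).

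**Figure D4:**
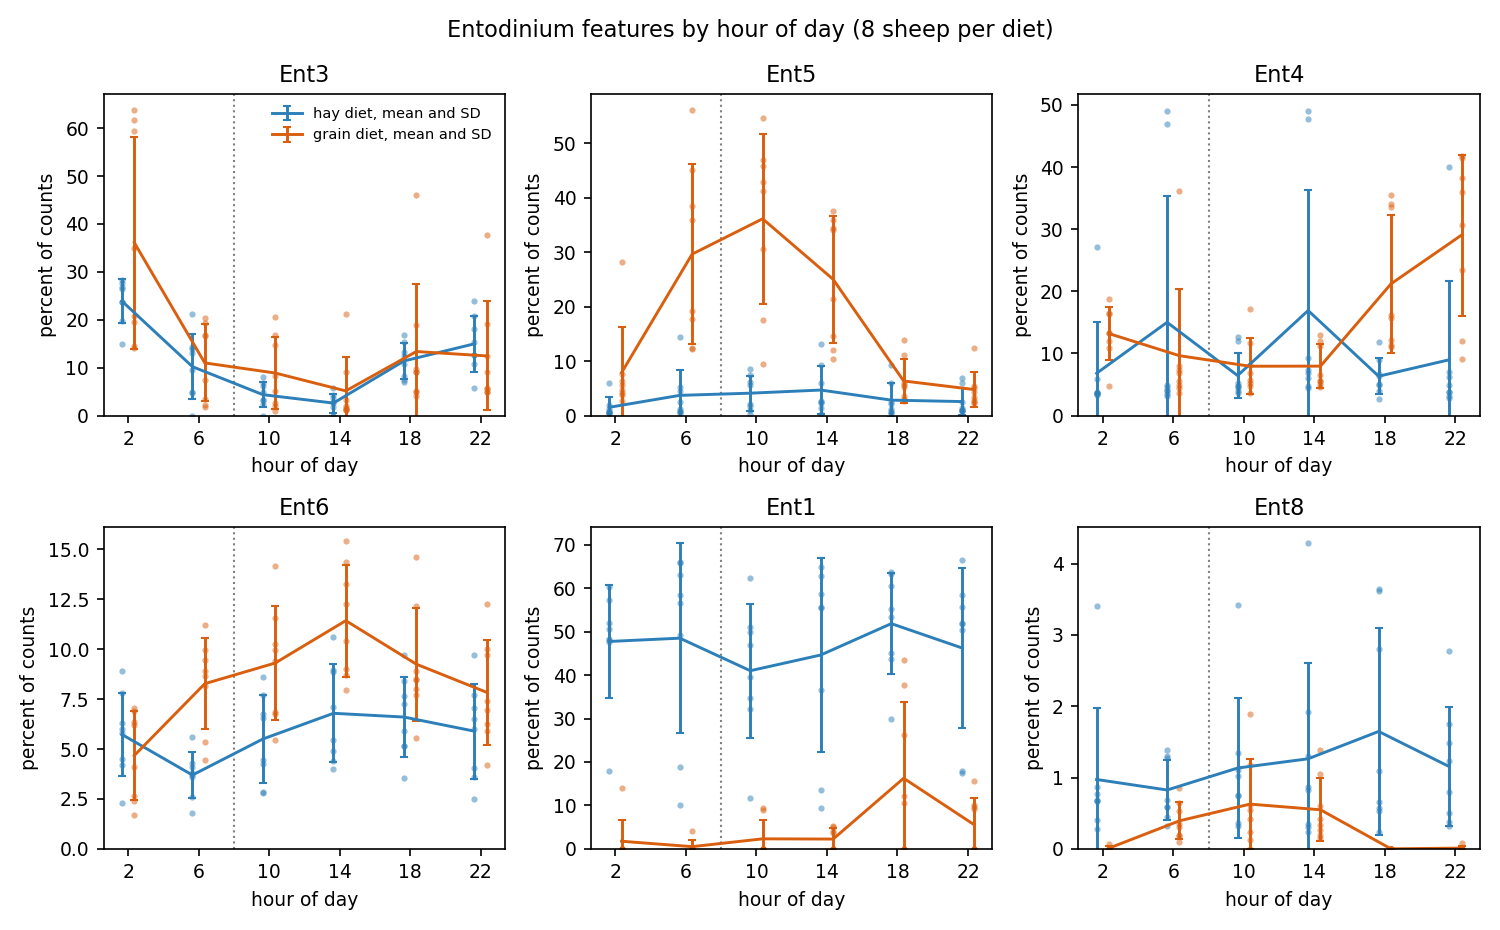
Percent of counts of Ent3, Ent5, Ent4, Ent6, Ent1 and Ent8 against hour of day, with 1 point per sample and lines for the mean and SD of 8 sheep on hay (blue) and on grain (orange), and a dotted line at feeding. Ent5 on grain stands at 36.2% at 10:00 and 4.79% at 22:00, and Ent3 is highest at 2:00 on both diets.

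The third comparison asked whether daily courses differed between diets. Ent5 and Ent4 differed in both tests given below, and Ent8 and Ent9 in edgeR alone. On grain the mean of Ent5 went from 7.89% at 2:00 (4.98% without sheep 5) to 36.2% at 10:00 and 4.79% at 22:00, and on hay it stayed between 1.52% and 4.69%. Ent4 on grain went from 7.94% at 10:00 to 29.0% at 22:00, and on hay its highest mean was 16.9% ± 19.5 at 14:00, where sheep 4 and 8 held 47.7% and 49.0% and the other 6 between 4.37% and 9.25%. Ent3 was highest at 2:00 and lowest at 14:00 on both diets, and no difference of its course was detected (edgeR adjusted p = 1, exact adjusted p = 0.447).

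In edgeR's test of diet by time 4 of 30 features passed and 8 had an unadjusted p under 0.05, namely Ent8 (adjusted p = 2.12e-16), Ent5 (0.000456), Ent4 (0.000456) and Ent9 (0.0238). All 4 were among 24 Entodinium features, and 4 passed when adjusted over the list alone, against 0 of 3 Dasytricha, 0 of 1 Polyplastron and 0 of 2 Trichostomatia features both ways. The same test made 45 false calls in 25 simulated datasets without change. An exact reassignment of diets over sheep on percents, added after the data were seen, kept Ent5 and Ent4 (adjusted p = 0.00233 each) and not Ent8 (0.243) or Ent9 (0.216). Under 26 alternative settings of edgeR, DESeq2 and limma, Ent5 and Ent4 each lost the call in 2, and Ent9 in 6. The highest adjusted p of Ent5 in these settings was 0.0817. Ent8 kept its call under all 26 alternative settings of edgeR, DESeq2 and limma (highest adjusted p = 7.77e-08). On grain it was seen in 8, 7 and 8 of 8 libraries at 6:00, 10:00 and 14:00. At 2:00, 18:00 and 22:00 it was seen in 1, 0 and 1. The exact test compares points of percent, where its grain means of 0 to 0.627% lie beside SDs of up to 1.46 on hay. Its miss there does not show that the courses of Ent8 were alike. Ent4 did not pass in edgeR without hay sheep 4 and 8 (adjusted p = 0.253), which does not show that these sheep carried the difference, since without them it stood at log2 fold changes of 1.75 (SE 0.45) at 18:00 and 2.46 (SE 0.58) at 22:00 against -0.27 (SE 0.20) at 14:00. The edgeR count was 2 without hay sheep 2. For genera the exact reassignment gave adjusted p of 0.114 for Entodinium, 0.259 for Dasytricha and 0.259 for Polyplastron, so the hay courses were not shown to differ from those on grain.

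Diets were also compared at each time of day, with 8 sheep each. Ent5 was higher on grain at 2:00, 6:00, 10:00 and 14:00, with the greatest log2 fold change of 2.30 (SE 0.63) at 10:00, where it stood at 36.2% ± 15.6 against 4.12% ± 3.19. Ent2 was higher on grain at 2:00, 14:00 and 18:00, at 18:00 with 22.3% ± 11.4 against 4.38% ± 2.63. At 6:00, 10:00 and 22:00 its means were 23.6%, 17.2% and 25.6% on grain against 4.83%, 5.00% and 8.68%. These differences did not pass (edgeR adjusted p = 0.0587, 0.0965 and 0.0795). Ent8 was lower on grain at 5 times, and at 18:00 had 0 counts on grain against 1.65% ± 1.46 on hay. Ent1 was lower on grain at 6:00, with 0.503% ± 1.42 against 48.5% ± 21.9, and at 14:00, with 2.25% ± 2.46 against 44.6% ± 22.3. At 2:00, 10:00, 18:00 and 22:00 its means were 1.75%, 2.30%, 16.3% and 5.55% on grain against 47.8%, 41.0%, 51.9% and 46.3%. Those differences did not pass (edgeR adjusted p = 0.0526, 0.0565, 0.284 and 0.290). The calls of Ent1 and Ent2 thus do not limit their differences to the hours called. With grain libraries at 0 given the level of Ent3 and totals not rescaled, the grain means of Ent1 were 11.2% ± 7.79 at 6:00 and 6.65% ± 6.31 at 14:00. At 2:00, 10:00, 18:00 and 22:00 they were 36.0%, 10.2%, 25.0% and 14.9%. Ent4 was higher on grain at 18:00 (log2 fold change 1.39, SE 0.41). At 14:00 it was lower on grain (-1.93, SE 0.62), but this call rested on hay sheep 4 and 8. Without them the log2 fold change was -0.27 (adjusted p = 0.289), and the mean of the other 6 hay sheep, 6.43% ± 1.80, lay below the 7.96% ± 3.49 on grain.

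The edgeR counts at 2:00, 6:00, 10:00, 14:00, 18:00 and 22:00 were 4, 3, 2, 5, 4 and 1 of 9, 9, 10, 10, 10 and 10 features, and 6, 4, 5, 5, 5 and 2 had an unadjusted p under 0.05. Besides the features above, Ent6 was lower at 2:00 (log2 fold change -1.54, SE 0.41), at 4.67% ± 2.21 on grain against 5.73% ± 2.09, Das1 was lower at 10:00 (-2.15, SE 0.67), at 9.84% ± 6.95 against 20.1% ± 13.9, and Ent9 was higher at 18:00, with 0 counts on hay. These values are relative to the scaling of each time point. With total-sum scaling the calls at 10:00 were 2 higher and 0 lower on grain in place of 1 and 1, those at 2:00 were 2 and 1 in place of 2 and 2, those at 14:00 were 3 and 1 in place of 2 and 3, and those at 6:00 were 4 and 2 in place of 1 and 2. The calls lost there were Ent6 at 2:00 (log2 fold change -0.29, SE 0.34, adjusted p = 0.511), Das1 at 10:00 (-1.03, SE 0.62, 0.189), and Ent4 (-1.09, SE 0.57, 0.120) and Ent8 (-1.20, SE 0.66, 0.120) at 14:00, so these 4 depended on the scaling. With DESeq2 there were 4 calls at 10:00 and 3 at 22:00. Without hay sheep 4 and 8, an alternative added after the data were seen, there were 4 at 22:00, and besides Ent4 at 14:00 the calls lost were Ent2 at 2:00 (log2 fold change 1.19, SE 0.46, against 1.28, SE 0.40, with all sheep; adjusted p = 0.0508) and Das1 at 10:00 (-1.55, SE 0.67; 0.0879). For Ent2 the fold was about as large, so its loss does not show that these sheep carried it.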

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

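The tests of Ent1 depth, of the ratios of Ent1 to Ent3, Das2 to Das1 and Ent7 to Ent3, of Ent9 in hay sheep 4 and 8, of diets reassigned on percents, and of other splits of the samples were chosen only after the result was seen, while the tests of hidden Ent1 and of the 10:00 library of hay sheep 4 were written before theirs.

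The first pattern is a gap in Ent1, which had 0 counts in 31 of 48 grain libraries and at least 1763 counts in the other 17, although 7 grain sheep had libraries of both kinds. Limited depth is argued against by that lowest count, which is 3.64% of its library and far above the 3 counts that a 0 allows. Ent1 was never far below Ent3 where it was seen on grain, with a lowest ratio of 0.958 (permutation p = 3.00e-05). Ent3 went down to 0.211 of Ent1 in grain libraries and to 0.0522 in the 61 libraries of either diet that held both. It was also at 0 in some hay libraries with Ent1, since it was seen in 44 of 48 and Ent1 in 48. A per-sample filter or merging step tied to Ent3, such as chimera removal, may thus have removed Ent1. Das2 to Das1 (lowest ratio 0.850 in 12 libraries, permutation p = 1.00e-05, the smallest they can give) and Ent7 to Ent3 (1.34 in 9 libraries, permutation p = 0.00013) had such an edge too. Each grain library at 0 was given as much Ent1 as its Ent3, with totals not rescaled, which overstates Ent1 on grain. It left 17.3% ± 5.64 (SD, n = 8) on grain against 46.7% ± 14.4 on hay, a ratio of 2.69 (exact permutation p = 0.000777). This argues against counts hidden up to the level of Ent3 as the whole cause of the diet difference. That level was inferred from the 17 grain libraries with Ent1. Larger hidden counts, or counts merged into a feature other than Ent3, are not excluded, and a change of the fauna by diet stays open beside the filter.

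The second pattern is a pair of hay sheep, 4 and 8, whose mean Ent1 was 25.0% and 23.9% against 45.7% to 58.2% in the other 6, and whose mean Ent4 was 21.5% and 30.8% against 3.93% to 5.49%. Samples swapped or mixed with grain sheep are argued against by Ent9, seen in 41 of 48 grain libraries and in 0 of the 12 libraries of these sheep, although it was also seen in only 8 libraries of the other hay sheep. The 10:00 library of sheep 4 alone is excluded, since without it the mean Ent1 of sheep 4 was 27.6%, still below 45.7%. With a mean of 25.0% over 6 libraries, leaving out any single library could not have reached 45.7%. That outcome was thus fixed by the mean, and it does not bear on sheep 8. Their Ent4 stood apart at 6:00 (47.0% and 49.0% against 3.10% to 4.87%) and at 14:00 (47.7% and 49.0% against 4.37% to 9.25%). At 2:00 sheep 4 held 3.63% Ent4 and sheep 8 27.2%, against 3.31% to 5.94%. At 18:00 they held 11.9% and 6.70%, against 2.75% to 8.95%. Their Ent1 at 18:00, 43.6% and 45.2%, lay within the 29.9% to 63.7% of the others, so they did not stand apart at every time. No biological explanation was tested, since the labels give no difference between the hay sheep.

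Among 51 groups of 8 values, 10 had a sample far from the others. The rule flags about 1 in 20, or 2.55, when groups are independent and values are normal. Percents of genera depend on each other and sheep means contain the single times, so 10 against 2.55 does not measure an excess. Dasytricha in grain sheep 5 was at 22.8% at 2:00 (nearest 5.79%) and 38.4% at 14:00 (nearest 15.5%), and Entodinium in the same sheep at 2:00 was at 75.7% (nearest 91.6%). In hay sheep 6, the mean Dasytricha was 18.1% (nearest 12.7%) and Entodinium at 18:00 was 62.4% (nearest 80.2%). In hay sheep 4, Polyplastron was at 52.7% at 10:00 (nearest 14.9%) and had a mean of 10.6% (nearest 4.96%). The others were Polyplastron at 3.93% in hay sheep 8 at 2:00 (nearest 2.03%), 13.9% in grain sheep 1 at 6:00 (nearest 6.85%) and 12.6% in grain sheep 3 at 14:00 (nearest 4.78%).

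The time course differed between diets in edgeR for Ent8 (adjusted p = 2.12e-16), Ent5 (0.000456), Ent4 (0.000456) and Ent9 (0.0238), and in the exact reassignment of diets for Ent5 and Ent4 (adjusted p = 0.00233 each) but not Ent8 (0.243) or Ent9 (0.216). The miss of Ent8 does not show alike courses, since it kept its call under all 26 alternative settings of edgeR, DESeq2 and limma. In those settings Ent5 and Ent4 each lost the call in 2, and Ent9 in 6. The Haptoria feature, used in no comparison, had 122 counts on hay and 0 on grain, above the 3 counts that a 0 allows.

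Chance was examined by 100 splits of the samples. For the diet test, where sheep were reassigned, the real split called 5 features and the highest other split 1. Only 1 split, the real one, reached the count. This is the lowest share that 100 splits can give, so chance is made unlikely but is not excluded. With times reordered within sheep, the real count for time on hay was 6 against a highest other of 2, and on grain 6 against 3, each reached by 1 split. This covers the counts and not each call, since these tests made 14 and 8 false calls in 25 simulated datasets without change. For diet by time, with sheep reassigned, the real count was 4 against 2, reached by 1 split. This too covers the count and not each call, since the test made 45 false calls in 25 such datasets. At single times the real counts and the highest other were 4 and 3 at 2:00, 3 and 1 at 6:00, 2 and 1 at 10:00, 5 and 2 at 14:00 and 4 and 3 at 18:00, each reached by 1 split, and 1 and 1 at 22:00, reached by 2 of 100. Without a filter on low counts the diet test called 176 of 214 features, but other splits called up to 165 (median 133), so counts near that size arose without the split by diet, and their cause was not tested.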

How the results depend on the processing

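Tests on feature percents, joint counting of Ent1 and Ent3, Ent1 at the level of Ent3, and omission of hay sheep 4 and 8 or of the 10:00 library of hay sheep 4 were chosen only after the results were seen. Of 256 values of the comparisons under alternatives, 222 kept their side of the threshold or stayed within 1.5 times the count, 29 moved, 3 lost the threshold, 1 passed it and 1 reversed. Of 589 for named taxa, 508 kept their side of the threshold, 75 lost it, 3 passed it and 3 reversed. The cause was not tested for any change below unless it is named. Between diets, 5 features passed, against 176 without a filter, 9 with limma on centred log-ratios, 12 without hay sheep 4 and 8, 8 in the exact test, and 6 to 9 with a sheep left out (9 without hay sheep 4). All 5 features kept their direction under every alternative that tested them, and Ent8 missed the threshold without a filter (adjusted p = 0.0652). For time on hay, 6 features became 3 with DESeq2, 0 with limma, 2 without hay sheep 4 and 8, 2 without the 10:00 library, 5 (2 shared) with joint counting, and 0 to 10 with a sheep left out (0 without sheep 6, 1 without 3, 2 without 2 or 4, 3 without 7, 10 without 1). On grain, 6 became 4 to 10 (10 without sheep 3 or 4). For diet by time, 4 became 2 in the exact test and 2 to 6 with a sheep left out (2 without hay sheep 2). At 6:00, 3 calls became 6 with total-sum scaling, and with DESeq2 2 became 4 at 10:00 and 1 became 3 at 22:00, where it became 4 without hay sheep 4 and 8. Genera between diets went from 0 calls to 2 on centred log-ratios and 0 to 1 with a sheep left out (1 without grain sheep 5), and the lists likewise 0 to 1. Polyplastron between diets, 0.208 points, reversed to -0.00917 (log2) with edgeR, and ran from -0.230 to 1.21 with a sheep left out (-0.107 without hay sheep 1 and -0.230 without hay sheep 5). Genera over time on hay went from 3 to 1 on centred log-ratios and 1 to 3 with a sheep left out (1 without sheep 1). Time took 51.0% of Shannon diversity on hay with joint counting, which passed, and 23.0% on grain with Ent1 at the level of Ent3 where it was at 0, which did not. At genus level Shannon diversity reversed to -0.0332, and the share of variation by diet and by time on grain became 13.5% and 15.0%, which missed the threshold. No genus was removed by the 0.01% filter, so leaving it out moved nothing.

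The sheep number as a block across diets joins different animals. Same-numbered sheep had a mean correlation of 0.200 (from -0.460 to 0.654), 6 of 8 above 0.1, and 2 of 8 correlated best with their own number, so the numbers were not taken as pairs. With that replicate block the diet test called 6 features, 4 of them shared, and Tri2 missed the threshold (adjusted p = 0.173), and genera gave 0. At single times it called 5, 3, 3, 4, 4 and 1. Without the sheep as a block within diets, 6 features passed over time on hay, 8 on grain and 8 for diet by time, and genera gave 3 and 0. Thinning to the smallest total left 5 features between diets, and shares under the floor of 3 counts could not be seen.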

Other observations

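The cosine fits to percents of features, the sum of Ent1 and Ent3, the steps around feeding and the value without the 10:00 library of hay sheep 4 were chosen only after the result was seen, while the tests of depth and of genus share for features found in 1 library were written before theirs.

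By cosine fits to percents, the features that passed over time in edgeR peaked on grain at hour 9.61 (Ent5), 9.63 (Ent10), 10.4 (Ent8), 13.8 (Ent6), 21.3 (Ent4) and 1.38 (Ent3), and on hay at 0.568 (Ent3), 2.83 (Ent18), 10.6 (Pol1), 11.9 (Ent5), 12.2 (Das1) and 22.2 (Das3). The fit of Pol1 did not pass (permutation adjusted p = 0.0553). The sum of Ent1 and Ent3 was 57.9% ± 17.0 (SD, n = 8) on hay and 19.3% ± 5.73 on grain (exact permutation p = 0.000155, the smallest the assignments can give).

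Around feeding, from 6:00 to 10:00, Entodinium on hay was lower in 8 of 8 sheep, with a mean of -19.3 points ± 16.9 (exact permutation p = 0.00781, the smallest 8 sheep can give), which missed the threshold over 14 comparisons (adjusted p = 0.109). Dasytricha on hay was higher in 6 of 8 sheep, by 10.8 points ± 16.7 (exact permutation p = 0.133). On grain the mean steps of Entodinium and Dasytricha were -0.132 and 0.459 points (exact permutation p = 0.953 and 0.906).

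Of the 214 features, 113 had counts in 1 library only, 79 of Entodinium, 18 of Dasytricha and 16 of Polyplastron, and 13 of them lay in the 10:00 library of hay sheep 4. No relation with depth was detected, since their number per library had a Spearman correlation of 0.116 with the total count (permutation p = 0.259) and a Pearson correlation of -0.00995 (permutation p = 0.923), or 0.0855 without the 2 farthest libraries. The test set beforehand would have excluded depth on a missed threshold, which leaves a weak relation open, so depth is not excluded. Sequence errors or rare variants of the abundant sequence of a genus may be a source, since the 34 features of Dasytricha and Polyplastron lay in libraries with 5.87 times the mean share of their genus (permutation p = 1.00e-05, the smallest they can give). Without that library the 23 others lay at 1.99 times (permutation p = 1.00e-05). This test does not separate errors from true rare variants, and no biological explanation was tested.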
